A study of Mus musculus with 13 samples.

How the data were processed

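Polyadenylated RNA of the mouse tibialis anterior was measured by RNA-seq in 13 libraries, 5 from WT, 4 from mdx and 4 from mdxTG mice. Per the labels' protocols, RNA was extracted with TRIzol, purified with DNase treatment on RNeasy columns, and made into libraries with a stranded mRNA kit. Per the submitters' processing notes, bcl2fastq 2.17, STAR and edgeR were used with the mouse build mm10; the STAR and edgeR versions, the read counter, its strand setting and the gene annotation were not given in the sources used here. The labels number the libraries within each genotype and also describe them by identifiers, which form 1 run of numbers in WT and another, interleaved between the genotypes, in mdx and mdxTG; what these mean is not given in the sources used here. If they mark cohorts, comparisons with WT do not separate cohort from genotype. The labels do not say that each library came from its own animal, so p-values measure the spread between these samples, which may be technical. The labels do not give the species or promoter of the transgene, so the Sspn level counts only those transgene reads that align to the mouse gene.

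The authors deposited the total, uniquely and multiply mapped read counts of each library and, as a fraction of the total, the share mapped in each way. The authors' expression sheet holds a normalized signal, named CPM in the sheet, in which a gene's reads are divided by an effective library size. Its columns sum to 839.6 to 1203.4 in units of 1000, so they are not plain CPM of the listed genes, and every value is a whole multiple of 1 step per library. With these steps 100% of the values came within 0.001 reads of a whole number, with a largest deviation of 2.8e-09 reads. The scaling factors per library implied by the deposited values multiply to 1, as edgeR's TMM factors do. The authors' deposited tables of comparisons give log2 fold changes, p-values and adjusted p-values in columns named logFC, PValue and padj. They hold only genes with an adjusted p under 0.01 and a log2 fold above 1 in size. Genes outside the sheet were not analysed here. Processing by the authors set the scaling: the factors were 0.831 to 0.932 in WT, 1.006 to 1.068 in mdx and 1.107 to 1.191 in mdxTG, and fold changes between groups rest on them.

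Libraries held 53.26 to 68.44 M reads, 80.94 to 88.62% uniquely mapped. Reads recovered over the listed genes came to 41.74 to 53.87 M per library, and the 10 most abundant genes took 17.79 to 28.42% of them. A gene with 3 reads had 0.0504 to 0.0818 normalized CPM, the level that a count of 0 still allows, for counting error only. No replicate pair agreed within sampling noise: the chi-square per degree of freedom between libraries of one group was 24.1 to 180.

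The main test was limma 3.58.1 in R 4.3.3, with an empirical Bayes trend, on log2 of the normalized CPM plus a pseudocount of 0.5, which understates changes of low genes. All 13 libraries entered 1 fit with 1 mean per genotype, and 3 comparisons were made, mdx against WT, mdxTG against mdx and mdxTG against WT. Genes needed 0.5 normalized CPM in 4 libraries, which kept 13831 of 13846. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and the threshold was 0.05. "Rose" and "fell" are used for genes past it. An exact two-sided permutation test was added for Sspn, Dmd and Utrn.

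Before the data were examined, 32 gene lists with 558 members were fixed, together with the tests, the alternatives and the rule for named genes; 31 lists were tested, since T, B and NK cells had fewer than 3 members kept (Cd4 and Ccl5). Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison; 525 members were measured. No list passed with an estimated correlation, where the lowest adjusted p was 0.3, 0.22 and 0.41 in the 3 comparisons. The fry test, which asks whether the genes of a list move one way on balance, passed 17, 9 and 19 lists. Named genes were Sspn, Dmd and Utrn; per comparison the 10 largest rises and falls among genes past the threshold without overlap between the groups and with a mean of at least 1 CPM in the higher group; and the 4 members with the smallest p of each list that passed and of 6 lists whether they passed or not; a few of these are not reported here. Coordinates are those of GENCODE M21, an annotation of mm10, matched by gene symbol for 98.9% of the listed genes; coordinates cover the whole gene.

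Genes that moved back were those past the threshold in mdx against WT and, in the opposite direction, in mdxTG against mdx. Both comparisons use the mdx libraries, so 100 sets of mdxTG libraries without a transgene effect were simulated, and the mdx libraries were divided 2 and 2 between the comparisons in all 6 ways (3 divisions, each way round). Before use, the tests were run on simulated counts with 200 changed genes. In mdx against WT, over 13822 genes, limma recovered 50.7% of 1.5-fold, 86.6% of 2-fold and 100% of 4-fold changes, with 7 false calls. In mdxTG against mdx, over 13817 genes, it recovered 46.3, 89.6 and 95.5%, and in mdxTG against WT, over 13808 genes, 58.2, 85.1 and 100%, with 7 false calls each. These simulated counts drew each gene independently and left most genes unchanged. They therefore do not give the false calls where genes vary together between libraries or where the scaling shifts many genes.

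The alternatives were pseudocounts of 0.1 and 2, no filter and a filter of 2 CPM, TMM and median-of-ratios rescaling, no variance trend, only the 2 groups compared in the fit, a replicate block, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. Plain CPM, the block with only 2 groups, and leaving out WT replicates 1 and 2 together were added after the data were seen. On the recovered reads edgeR called 4813, 3917 and 7494 genes in mdx against WT, mdxTG against mdx and mdxTG against WT. WT and mdx libraries share replicate numbers in the labels, and the deviations of same-numbered libraries from their group means correlated across genes at 0.34, 0.45, 0.33 and 0.18, all over 0.1, so these numbers were taken to pair the libraries of WT and mdx. The pairing rests on these correlations, not on the labels, and replicates 3 and 4 correlated better with another number (0.36 and 0.48), so 2 of 4 correlated best with their own; the reported fit leaves the pairing out, and the block is given as an alternative. Of the 1073, 748 and 1857 genes in the authors' deposited tables for mdx against WT, mdxTG against mdx and mdxTG against WT, 1068, 737 and 1849 also passed the threshold of 0.05 here in the same direction. At the limits those tables keep to, limma called 800, 574 and 1459 genes, of which 783, 558 and 1436 are in the tables. Figures were drawn with matplotlib 3.10.9.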

Results

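RNA from the tibialis anterior, a fast muscle of the lower leg, was sequenced in 13 mouse libraries. The 5 WT libraries came from wild-type mice and the 4 mdx libraries from mice with a mutated dystrophin gene, the model of Duchenne muscular dystrophy. The 4 mdxTG libraries came from mdx mice that also carried a transgene for sarcospan (Sspn), a small membrane protein of the dystrophin-glycoprotein complex. The libraries held 53.26 to 68.44 M reads, and 41.74 to 53.87 M reads per library were assigned to the 13846 listed genes. A count of 3 reads corresponded to 0.0504 to 0.0818 normalized CPM, depending on the library.

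Sspn and Dmd were examined first because the transgene and the mutation define the groups. Sspn (chromosome 6, 145931641 to 145965223, mm10) had a level of 114 ± 4.9 normalized CPM in mdx (SD, n = 4) and 118 ± 13.3 in WT (SD, n = 5). In mdxTG it reached 1740 ± 185 (SD, n = 4), a rise of 15.2-fold over mdx (log2 fold 3.92 ± 0.10 SE, limma adjusted p = 2.89e-12). All 4 mdxTG libraries lay above all mdx libraries, with an exact two-sided permutation p of 0.029, the smallest that 70 arrangements allow. Dmd (chromosome X, 82948870 to 85206141), which encodes dystrophin, fell from 223 ± 55.4 normalized CPM in WT (SD, n = 5) to 52.6 ± 4.44 in mdx (SD, n = 4). Its log2 fold was -2.03 ± 0.17 (SE, limma adjusted p = 1.69e-06), and the exact permutation p was 0.0079, the smallest possible. In mdxTG the Dmd level was 59.2 ± 3.69 (SD, n = 4), with a log2 fold of 0.17 ± 0.18 against mdx (limma adjusted p = 0.524), and -1.86 ± 0.17 against WT (limma adjusted p = 5.98e-07). Utrn (chromosome 10, 12382188 to 12869365), which encodes the dystrophin relative utrophin, had levels of 66.9 ± 21.3 in WT, 70 ± 16.7 in mdx and 84.8 ± 17.7 in mdxTG. None of its 3 comparisons passed the threshold, with log2 folds of 0.09 ± 0.22, 0.28 ± 0.23 and 0.37 ± 0.22 (SE) for mdx against WT, mdxTG against mdx and mdxTG against WT, and limma adjusted p of 0.779, 0.408 and 0.17. Without WT replicate 5 the Utrn difference between mdxTG and WT passed (log2 fold 0.52, adjusted p = 0.0463), as it did in plain CPM (0.75, adjusted p = 0.0152). The same difference passed with the replicate number as a block in the fit of all libraries (log2 fold 0.52, adjusted p = 0.0133), although the mdxTG numbers were not taken to pair. With the replicate number as a block in a fit of WT and mdx alone, Utrn was higher in mdx (log2 fold 0.24, adjusted p = 0.0208).

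**Figure D1:**
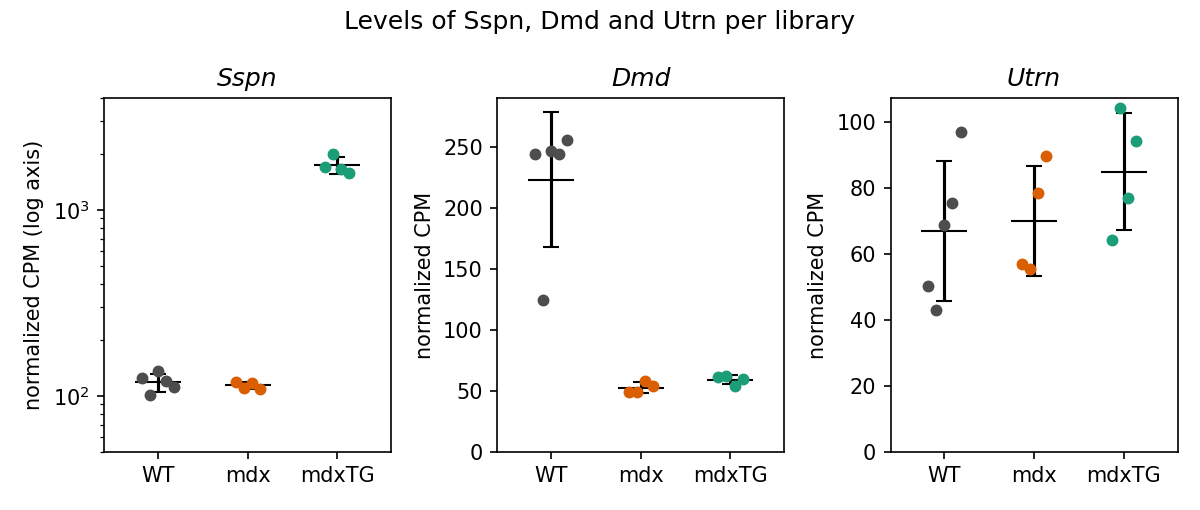
Normalized CPM of Sspn (log axis), Dmd and Utrn in the WT, mdx and mdxTG libraries; points are libraries, the bar is the group mean and the whiskers are 1 SD. Sspn lay near 114 and 118 in mdx and WT and at 1740 in mdxTG, and Dmd fell from 223 in WT to 52.6 in mdx.

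The 3 genotypes separated along the first principal component, which held 57.2% of the variance. WT libraries had scores from -51.2 to -33.9, mdx libraries from -0.9 to 12.7 and mdxTG libraries from 36.6 to 45.6. The second component, with 17.3% of the variance, set mdx apart, with scores from -34.6 to -21.0.

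**Figure D2:**
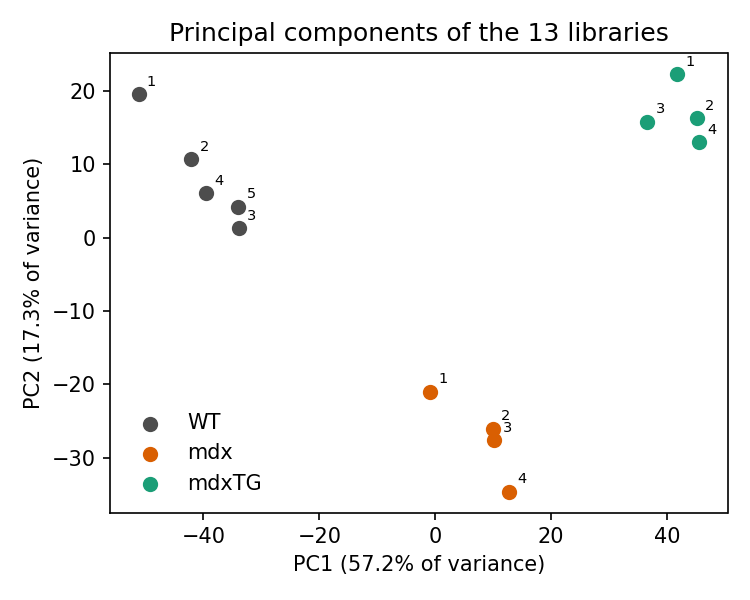
Scores of the 13 libraries on principal components 1 and 2 of log2 normalized CPM; each point is a library numbered by its replicate and coloured by genotype. On component 1 the mdx libraries (-0.9 to 12.7) lay between WT (-51.2 to -33.9) and mdxTG (36.6 to 45.6).

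The comparison of mdx with WT addressed the effect of the dystrophin mutation. The lists of regenerating fibres, dividing cells, macrophages, interferon response, matrix, cytoskeleton and integrin adhesion moved upward. Those of energy metabolism (for glycolysis not in plain CPM), mitochondrially encoded genes, fast fibres, nerve, blood and smooth muscle moved downward. These 16 lists passed the threshold at the preset correlation and 0 with an estimated correlation. Embryonic myosin heavy chain Myh3 went from 10.9 ± 15.9 normalized CPM in WT (SD, n = 5) to 174 ± 92 in mdx (SD, n = 4), and perinatal myosin Myh8 from 5.39 ± 3.08 to 102 ± 40.3. Macrophage elastase Mmp12 went from 0.261 ± 0.175 to 15 ± 5.81. Of 13831 genes tested, 4782 changed, 2559 of them upward and 2223 downward.

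In mdx, 19 of the 21 satellite cell and regeneration genes rose and 0 fell, and 20 rose adjusted over the list alone. The acetylcholine receptor subunit Chrna1 rose by a log2 fold of 1.77 ± 0.13 (SE, adjusted p = 5.88e-07), Myh8 by 4.13 ± 0.33 and the embryonic light chain Myl4 by 2.95 ± 0.24. Of 18 proliferation genes 17 rose, also adjusted over the list alone, among them the mitotic kinase Cdk1 (2.02 ± 0.17) and the topoisomerase Top2a (2.79 ± 0.24). Macrophage genes rose in 18 of 20 cases (19 adjusted over the list alone), led by the lipid receptor Trem2 (3.33 ± 0.19), galectin-3 Lgals3 (3.47 ± 0.21) and Gpnmb (3.61 ± 0.31). The camera adjusted p was 3.92e-12 for regeneration, 4.57e-13 for proliferation and 3.92e-12 for macrophages, against adjusted p = 0.35, 0.3 and 0.35 with an estimated correlation. Interferon response genes rose in 8 of 20 cases (8 adjusted over the list alone; adjusted p = 0.00498, and adjusted p = 0.56 with an estimated correlation), led by Mx1 (1.07 ± 0.15). Without mdx replicate 4 the interferon list had an adjusted p of 0.0503.

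Among matrix genes, 14 of 24 fibrillar collagen and matrix genes rose (15 adjusted over the list alone), as did 18 of 24 matrix remodelling genes (19 adjusted over the list alone), while 2 remodelling genes fell. Col5a3 rose by a log2 fold of 1.27 ± 0.11 (SE), periostin Postn by 1.90 ± 0.23 and lumican Lum by 1.28 ± 0.18. The protease inhibitor Timp1 rose by 3.26 ± 0.24 and the protease Mmp3 by 3.11 ± 0.29. These lists had camera adjusted p of 1.24e-05 and 1.69e-07, and adjusted p = 0.54 and 0.52 with an estimated correlation. Matrix genes also varied between libraries of one genotype: on the main axis of that variation the median loading of the fibrillar collagen and matrix list lay at the 98.9th percentile of all genes. Loadings on this axis correlated with the log2 folds of mdx against WT across genes at a Spearman rho of 0.26. In the cytoskeleton list 13 of 25 genes rose and 2 fell (13 and 3 adjusted over the list alone; adjusted p = 3.86e-04, and adjusted p = 0.35 with an estimated correlation), with Tubb6 at 2.28 ± 0.19 and Krt18 at 1.61 ± 0.17. In the integrin adhesion list 10 of 25 genes rose and 2 fell (10 and 4 adjusted over the list alone; adjusted p = 0.0341, and adjusted p = 0.54 with an estimated correlation). The fibronectin receptor subunit Itga5 rose by 0.81 ± 0.09 and the laminin receptor subunit Itga7 by 0.62 ± 0.08. The integrin list no longer passed without WT replicate 2 (adjusted p = 0.0571), mdx replicate 3 (0.0777), mdx replicate 4 (0.0512) or both WT replicates 1 and 2 (0.0971).

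The metabolic lists moved downward relative to the other genes. In the list of the TCA cycle and fatty acid oxidation 20 of 26 genes fell (21 adjusted over the list alone), with the fatty acid carrier Fabp3 at a log2 fold of -1.14 ± 0.22 (SE) and the dehydrogenase Acadm at -0.50 ± 0.09. In the oxidative phosphorylation list 12 of 28 genes fell (20 adjusted over the list alone), led by Cox6a2 (-0.69 ± 0.15), and in glycolysis and glycogen 8 of 20 fell (8 adjusted over the list alone), led by the phosphorylase Pygm (-0.61 ± 0.12). Camera adjusted p were 1.80e-07, 1.66e-05 and 0.00767, and adjusted p = 0.35, 0.54 and 0.54 with an estimated correlation. In plain CPM, without the authors' scaling factors, 5, 1 and 2 genes of these lists fell, 5 glycolysis genes rose, and the glycolysis median turned from -0.21 to 0.02. Of 12 mitochondrially encoded genes 8 fell (11 adjusted over the list alone; adjusted p = 4.07e-04, and adjusted p = 0.35 with an estimated correlation), and 3 fell in plain CPM. The most abundant of those named, mt-Nd5, fell by a log2 fold of 0.45, from 20300 ± 2010 to 14800 ± 865 normalized CPM; it did not pass with only WT and mdx in the fit (adjusted p = 0.0554, or 0.0876 with the replicate block as well), nor in plain CPM (log2 fold -0.22, adjusted p = 0.139). The low levels of mt-Nd3, mt-Atp8, mt-Co2, mt-Atp6 and mt-Co3 (means of 0.206 to 28.2 normalized CPM in WT and mdx) were uncertain because nuclear copies could take their reads. The WT level of mt-Co3 was 28.2 ± 49.5 (SD, n = 5). Counts and tests of the mitochondrially encoded list include these genes. Mitochondrial genes took 12.73 to 19.15% of gene reads in WT, 10.5 to 14.75% in mdx and 8.78 to 10.89% in mdxTG.

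Fast-fibre genes fell in 5 of 14 cases (7 adjusted over the list alone; adjusted p = 0.0173, and adjusted p = 0.54 with an estimated correlation). The kinase Mylk2 had a log2 fold of -0.65 ± 0.10 (SE), the actin crosslinker Actn3 -0.54 ± 0.13 and the fast myosin Myh4 -0.69 ± 0.20. The fast-fibre list had an adjusted p of 0.0546 without WT replicate 2 and 0.0971 without both WT replicates 1 and 2; in plain CPM 3 of its genes fell and 1 rose, and its median was -0.19 in place of -0.42. Myh4 had an adjusted p of 0.0507 without mdx replicate 1, 0.0504 without mdx replicate 2, 0.0545 with only WT and mdx in the fit and 0.0793 with the replicate block as well. Mybpc2 (-0.46 ± 0.14) had an adjusted p of 0.0675 without mdx replicate 2, and of 0.137 in plain CPM, where its log2 fold was -0.23. Nerve and Schwann cell genes fell in 9 of 12 cases while 1 rose (10 and 1 adjusted over the list alone; adjusted p = 3.86e-04, and adjusted p = 0.54 with an estimated correlation), with the myelin gene Prx at -1.25 ± 0.20. Blood genes fell in 5 of 6 cases (6 adjusted over the list alone; adjusted p = 0.00969, and adjusted p = 0.54 with an estimated correlation), with the haemoglobin gene Hba-a1 at -1.04 ± 0.29. The haemoglobin gene Hbb-bs (-0.92 ± 0.28) did not pass without mdx replicate 2 (adjusted p = 0.0712), mdx replicate 3 (0.0555) or both WT replicates 1 and 2 (0.0653), nor in plain CPM (0.0549). Smooth muscle and pericyte genes fell in 5 of 10 cases (5 adjusted over the list alone; adjusted p = 0.0341, and adjusted p = 0.54 with an estimated correlation), with smooth muscle myosin Myh11 at -0.78 ± 0.10. That list did not pass without WT replicate 4 (0.0619), WT replicate 5 (0.0591), mdx replicate 1 (0.0934) or mdx replicate 2 (0.0541). Falls in the nerve, blood and smooth muscle lists were counted with the authors' scaling, and in plain CPM the median of all genes shifted to 0.20.

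In the dystrophin-glycoprotein complex list 3 of 16 genes rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.541). Besides Dmd, the members with the smallest p were the syntrophins Sntb1 (log2 fold 1.00 ± 0.20 SE) and Sntb2 (0.55 ± 0.15) and dystrobrevin Dtna (0.38 ± 0.08), which rose. Of 21 targets of the transcriptional coactivators YAP and TAZ 4 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.378), with Ankrd1 at 2.84 ± 0.30, while the growth factor regulator Crim1 fell by 1.00. In plain CPM 7 genes of the dystrophin-glycoprotein complex rose and 1 fell, as did 7 and 1 YAP and TAZ targets, and 16 and 0 integrin adhesion genes. The other lists below the threshold were TGF-beta signalling (4 rose and 1 fell of 18), basement membrane (4 and 1 of 14), dystroglycan glycosylation (0 and 3 of 12), muscle atrophy (5 and 5 of 17) and immediate early and heat shock (5 and 2 of 16). Adjusted over the list alone these counts were 4 and 1, 5 and 1, 0 and 3, 5 and 7, and 6 and 2. Calcium handling (2 and 3 of 16), slow fibres (2 and 5 of 14), fibro-adipogenic progenitors (2 and 0 of 12), endothelial cells (0 and 2 of 12), adipocytes (1 and 0 of 11), neutrophils and mast cells (1 and 0 of 6), tenocytes (0 and 0 of 9) and cytosolic ribosomal proteins (1 and 0 of 24) did not pass either. Adjusted over the list alone these were 2 and 1, 2 and 5, 2 and 0, 0 and 0, 1 and 0, 1 and 0, 0 and 0, and 1 and 0. The counts of all these lists rest on the authors' scaling, and in plain CPM the median of all genes shifted to 0.20. Leaving out 1 library brought endothelial cells past the threshold without WT replicate 1 (0.0151) or mdx replicate 4 (0.0266), and TGF-beta signalling without WT replicate 5 (0.0484). Basement membrane passed without WT replicate 4 (0.0491) or 5 (0.0353), or mdx replicate 1 (0.031) or 2 (0.0279). With the replicate block, basement membrane (adjusted p = 0.00849) and TGF-beta signalling (0.0393) passed and smooth muscle and pericytes did not (0.0505). With the block and only WT and mdx in the fit, basement membrane (6.89e-05), TGF-beta signalling (0.0211), endothelial cells (0.0459) and ribosomal proteins (0.00911) passed. In plain CPM the slow-fibre list, which also holds the fast oxidative myosin Myh2, passed downward (0.00227, against 0.21 as reported), with 4 genes fallen and 2 risen. Endothelial cells also passed without both WT replicates 1 and 2 (0.0281). The fry test passed immediate early and heat shock genes upward (adjusted p = 0.0165).

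The 10 largest rises in mdx were Myh3, Mmp12, Myh8, the muscle fusion gene Mymk, Gm28438, Gm10036, Gpnmb, Lgals3, Gm48395 and Mpeg1, with log2 folds from 4.55 ± 0.61 for Myh3 to 3.42 ± 0.34 (SE) for Mpeg1. Gm28438 and Gm10036 are pseudogenes and their values were uncertain, since parent genes could share their reads. The 10 largest falls included the securin gene Pttg1 (chromosome 11, 43420250 to 43426251), which fell from 52.1 ± 8 to 1.6 ± 0.244 normalized CPM, and the clock-controlled factor Hlf, which fell from 24.8 ± 3.66 to 3.96 ± 0.922. Ppp1r1a fell from 34 ± 10.6 to 4.86 ± 0.34, and 9930111J21Rik2 from 3.62 ± 1.41 to 0.0251 ± 0.0235, with 5 reads in mdx. The zinc-finger gene Zfp970 (chromosome 2, 177464733 to 177478129) and its neighbours Gm14326, Gm14325 and Gm14403 were near 0 in mdx replicates 2 and 3, whereas Zfp970 was at 4.91 and 5.68 normalized CPM in mdx replicates 1 and 4. DESeq2 on recovered reads did not call these 4 genes (adjusted p from 0.118 to 0.192), nor edgeR Gm14325 (0.0541). The ventricular light chains Myl2 (-2.96 ± 0.94) and Myl3 (-2.62 ± 0.65) had WT means of 196 ± 369 and 194 ± 313, with the highest values in WT replicate 1. Myl2 did not pass without mdx replicate 2 (adjusted p = 0.071) or mdx replicate 4 (0.0562).

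In mdx against WT 3690 of the 13831 genes tested (26.7%) had no overlap between the libraries of the groups, where chance alone gives 1.59%; 3497 of them were among the changed genes. The authors' scaling factors (0.831 to 0.932 in WT, 1.006 to 1.068 in mdx) moved the split of calls, since 53.5% of the changed genes were higher in normalized CPM and 87.5% in plain CPM, where the median of all genes shifted to 0.20.

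The comparison of mdxTG with mdx, the purpose of the series, addressed the effect of the sarcospan transgene in dystrophic muscle. The lists of cytoskeleton, immediate early and heat shock, and blood genes moved upward, and those of proliferation, glycolysis, fast fibres, oxidative phosphorylation, and the TCA cycle and fatty acid oxidation downward. These 8 lists passed the threshold at the preset correlation and 0 with an estimated correlation. The annexin Anxa8 went from 2.66 ± 1.08 normalized CPM in mdx to 263 ± 52.2 in mdxTG (SD, n = 4 each), and the metallothionein Mt3 from 3.43 ± 0.77 to 236 ± 36.2. The immediate early factor Egr1 went from 13.1 ± 4.61 to 106 ± 16.1. Of 13831 genes 3922 changed, 2133 upward and 1789 downward.

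Of 16 immediate early and heat shock genes 12 rose and 0 fell (12 and 1 adjusted over the list alone; adjusted p = 6.67e-07, and adjusted p = 0.22 with an estimated correlation). Egr1 rose by a log2 fold of 3.02 ± 0.21 (SE, adjusted p = 1.25e-07), Egr2 by 1.96 ± 0.18 and the small heat shock protein gene Hspb1 by 1.01 ± 0.13. In the cytoskeleton list 11 of 25 genes rose and 0 fell (12 and 2 adjusted over the list alone; adjusted p = 0.0147, and adjusted p = 0.65 with an estimated correlation). Nestin (Nes) rose by 2.19 ± 0.16, the lamin gene Lmna by 0.91 ± 0.07 and the repair-associated Xirp1 by 2.25 ± 0.22. Blood genes were at the threshold (adjusted p = 0.0499, and adjusted p = 0.89 with an estimated correlation), with 2 of 6 risen (5 adjusted over the list alone), Alas2 by 0.93 ± 0.23 and Hba-a1 by 1.01 ± 0.30. The blood list did not pass without WT replicate 1 (0.0535) or 5 (0.0517), mdx replicate 2 (0.0803), 3 (0.0756) or 4 (0.0561), or mdxTG replicate 3 (0.0974), nor in plain CPM (0.112), with a pseudocount of 2 (0.0677) or a filter of 2 CPM (0.081), nor by fry (0.0547). Hba-a1 did not pass without mdx replicate 2 (adjusted p = 0.0669), mdxTG replicate 1 (0.0599) or mdxTG replicate 3 (0.0703). Hbb-bs (0.81 ± 0.30, adjusted p = 0.0563) passed without WT replicate 2 (0.0259), mdx replicate 1 (0.0235) or mdxTG replicate 4 (0.023).

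Glycolysis and glycogen genes fell in 15 of 20 cases (16 adjusted over the list alone; adjusted p = 2.49e-07, and adjusted p = 0.58 with an estimated correlation). On the log2 scale the phosphorylase kinase subunit Phkg1 fell by 1.00, the glucose transporter Slc2a4 had -0.84 ± 0.08 (SE), and phosphofructokinase Pfkm -0.71 ± 0.11. In oxidative phosphorylation 11 of 28 genes fell (15 adjusted over the list alone; adjusted p = 5.49e-05, and adjusted p = 0.89 with an estimated correlation), led by Sdha (-0.50 ± 0.09). In the TCA cycle and fatty acid oxidation 11 of 26 fell and 2 rose (11 and 2 adjusted over the list alone; adjusted p = 0.0235, and adjusted p = 0.89 with an estimated correlation), led by Acadm (-0.55 ± 0.10), and this list had an adjusted p of 0.0523 without mdxTG replicate 2 and 0.0547 by fry. In plain CPM 14, 4 and 4 genes of these 3 lists fell. Atp5a1 (-0.39 ± 0.09) did not pass in plain CPM (adjusted p = 0.0599). Fast-fibre genes fell in 6 of 14 cases (9 adjusted over the list alone; adjusted p = 0.00188, and adjusted p = 0.65 with an estimated correlation), with the calcium store protein Casq1 at -0.94 ± 0.11, parvalbumin Pvalb at -0.95 ± 0.19 and Myh4 at -0.82 ± 0.21. Proliferation genes fell in 11 of 18 cases (13 adjusted over the list alone; adjusted p = 3.49e-05, and adjusted p = 0.65 with an estimated correlation), with the replication gene Mcm2 at -0.58 ± 0.10 and Cdk1 at -1.02 ± 0.18.

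Regeneration genes went both ways. In the satellite cell and regeneration list 11 of 21 genes fell and 5 rose (12 and 5 adjusted over the list alone; adjusted p = 0.168). The acetylcholine receptor subunit Chrnd rose by a log2 fold of 3.30 ± 0.18 (SE), the adhesion molecule Ncam1 by 1.81 ± 0.22 and Sox4 by 1.31 ± 0.20, while the myogenic factor Myf5 fell by 0.90. This list passed without WT replicate 3 (0.0492) or mdx replicate 1 (0.0427). It also passed downward in plain CPM (0.0256), but relative to the other genes, since the median of all genes there shifted to 0.13. The counts of falls rest on the authors' scaling. Macrophage genes fell in 6 of 20 cases and rose in 2 (6 and 2 adjusted over the list alone; adjusted p = 0.147). The 2 that rose were Lgals3 (2.43 ± 0.22) and Cd68 (1.63 ± 0.23), and osteopontin Spp1 (-2.44 ± 0.34) and Trem2 (-1.07 ± 0.20) fell. The macrophage list passed without WT replicate 1 (0.0358) or mdx replicate 1 (0.0274), and, relative to the other genes, in plain CPM (0.0183). In the fibrillar collagen and matrix list 3 of 24 genes rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p = 0.074), with Lum at 1.12 ± 0.19, Col5a3 at 0.56 ± 0.12, elastin Eln at -0.63 ± 0.15 and decorin Dcn at 0.68 ± 0.23. The collagen list passed without WT replicate 1 (0.0255), mdx replicate 3 (0.0296) or 4 (0.0137), or mdxTG replicate 1 (0.00529) or 3 (0.0406). Dcn did not pass without mdx replicate 1 (0.121) or 2 (0.0806) or mdxTG replicate 2 (0.105), 3 (0.0767) or 4 (0.0765).

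In the dystrophin-glycoprotein complex list 2 of 16 genes rose, Sspn and the sarcoglycan Sgce (log2 fold 0.44 ± 0.13 SE), and 2 fell, among them Sntb1 (-1.12 ± 0.21); the counts were also 2 and 2 adjusted over the list alone (adjusted p = 0.621). Sgce did not pass without mdx replicate 1 (0.0578) or 2 (0.0543) or mdxTG replicate 4 (0.0535). Integrin adhesion genes rose in 8 of 25 cases and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.207), with Itgav at 0.88 ± 0.11 and Lims1 at 0.80 ± 0.12. Of 21 YAP and TAZ targets 2 rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.916), with Igfbp3 at -1.04 ± 0.17, Fjx1 at 0.77 ± 0.19, Gadd45a at 0.69 ± 0.18 and Ajuba at -0.34 ± 0.10. Ajuba did not pass without mdx replicate 3 (0.0645) or mdxTG replicate 1 (0.0603), nor in plain CPM (log2 fold -0.21, adjusted p = 0.153). In plain CPM 10 integrin adhesion genes rose and 0 fell, against 4 and 2 of the dystrophin-glycoprotein complex and 4 and 1 YAP and TAZ targets. The other lists below the threshold were muscle atrophy (7 rose and 2 fell of 17), TGF-beta signalling (5 and 4 of 18), matrix remodelling (4 and 4 of 24), basement membrane (2 and 0 of 14), dystroglycan glycosylation (2 and 0 of 12), calcium handling (4 and 5 of 16) and slow fibres (2 and 0 of 14). Adjusted over the list alone these were 8 and 3, 7 and 4, 5 and 4, 1 and 0, 2 and 0, 4 and 5, and 2 and 0. Interferon response (3 and 3 of 20), mitochondrially encoded (0 and 3 of 12), adipocytes (3 and 2 of 11), smooth muscle and pericytes (2 and 0 of 10), nerve and Schwann cells (1 and 0 of 12), fibro-adipogenic progenitors (1 and 0 of 12), neutrophils and mast cells (0 and 1 of 6), endothelial cells (0 and 0 of 12), tenocytes (0 and 0 of 9) and cytosolic ribosomal proteins (0 and 0 of 24) did not pass either. Adjusted over the list alone these were 3 and 4, 0 and 2, 3 and 2, 1 and 0, 0 and 0, 1 and 0, 0 and 1, 0 and 0, 0 and 0, and 0 and 0. Leaving out 1 library brought 4 further lists past the threshold, muscle atrophy (0.0416) and ribosomal proteins (0.0278) without mdx replicate 2, and basement membrane (0.0276) and tenocytes (0.0393) without mdxTG replicate 1. In plain CPM the mitochondrially encoded list passed downward (0.0351, against 0.168 as reported), with 2 genes fallen and 1 risen. The fry test passed muscle atrophy (adjusted p = 0.00128), the dystrophin-glycoprotein complex (0.00188), which holds Sspn itself, and dystroglycan glycosylation (0.0176), all upward.

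The 10 largest rises were Anxa8, Mt3, Atp13a4, Sspn, the ubiquitin hydrolase Uchl1, Msln, Perp, Gsta1, Sprr1a and Ndrg4, with log2 folds from 6.42 ± 0.26 for Anxa8 to 3.54 ± 0.12 (SE) for Ndrg4. Atp13a4 (chromosome 16, 29395853 to 29544864) had 7 reads over the mdx libraries and 6791 over the mdxTG libraries, and the glutathione transferase Gsta1 had 17 and 1630. The 10 largest falls were Mettl11b, Mmp12, Fam57b, Arrdc2, Gadl1, Spp1, Gm28286, Myh3, Fgfbp1 and Mettl21c. Mettl11b fell from 13.2 ± 3.13 to 1.56 ± 0.492 normalized CPM, Fam57b from 54.6 ± 7.75 to 8.67 ± 2.47 and Mmp12 from 15 ± 5.81 to 1.95 ± 0.643. Myh3 (-2.21 ± 0.64) did not pass without mdx replicate 3 (adjusted p = 0.0536), mdx replicate 4 (0.0544) or mdxTG replicate 2 (0.0502).

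In mdxTG against mdx 4569 of the 13831 genes tested (33.0%) had no overlap between the groups, where chance gives 2.86%; 3533 of them were among the changed genes. Of the changed genes 54.4% were higher in normalized CPM and 78.1% in plain CPM, where the median of all genes shifted to 0.13.

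The comparison of mdxTG with WT addressed what differed from healthy muscle with the transgene present. The lists of matrix, basement membrane, cytoskeleton, regeneration, proliferation, macrophage, and immediate early and heat shock genes were higher in mdxTG, and those of metabolic, mitochondrially encoded and fast-fibre genes lower. These 13 lists passed the threshold at the preset correlation and 0 with an estimated correlation. Mt3 had 236 ± 36.2 normalized CPM in mdxTG (SD, n = 4) and 1.22 ± 0.186 in WT (SD, n = 5), and Lgals3 had 408 ± 40 and 6.69 ± 2.69. Of 13831 genes 7468 changed, 3967 upward and 3501 downward.

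Fibrillar collagen and matrix genes rose in 18 of 24 cases and matrix remodelling genes in 18 of 24 with 1 fallen (18 and 0, and 19 and 1, adjusted over the list alone). Col5a3 had a log2 fold of 1.84 ± 0.11 (SE), Lum 2.40 ± 0.18 and Timp1 3.68 ± 0.24. Cytoskeleton genes rose in 16 of 25 cases and 3 fell (16 and 3 adjusted over the list alone), with Lmna at 1.47 ± 0.07 and Nes at 3.08 ± 0.15. Regeneration genes rose in 16 of 21 cases, macrophage genes in 17 of 20 and proliferation genes in 17 of 18 with 1 fallen, and the counts were equal adjusted over the list alone. Chrnd had a log2 fold of 4.24 ± 0.17, Lgals3 5.90 ± 0.21, Cd68 4.14 ± 0.22 and Kif11 1.60 ± 0.13. Immediate early and heat shock genes rose in 14 of 16 cases with 1 fallen (14 and 1 adjusted over the list alone), with Egr1 at 4.05 ± 0.20 and Atf3 at 2.38 ± 0.17. Camera adjusted p ran from 1.66e-05 to 1.05e-04 over these 7 lists, and from adjusted p = 0.41 to adjusted p = 0.67 with an estimated correlation. Basement membrane genes rose in 9 of 14 cases and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.0311, and adjusted p = 0.75 with an estimated correlation), with Col18a1 at 1.37 ± 0.17 and Col15a1 at 1.54 ± 0.21. The basement membrane list did not pass without WT replicate 1 (0.061), WT replicate 2 (0.0627), both of these (0.137) or mdxTG replicate 4 (0.0522), nor in plain CPM (0.146).

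Oxidative phosphorylation genes fell in 27 of 28 cases, TCA cycle and fatty acid oxidation genes in 21 of 26, glycolysis and glycogen genes in 17 of 20, mitochondrially encoded genes in 10 of 12 and fast-fibre genes in 11 of 14. Adjusted over the list alone the numbers were 28, 21, 17, 10 and 12, and 1 fast-fibre gene then rose. In plain CPM 11, 11, 10, 9 and 11 fell. Acadm had a log2 fold of -1.05 ± 0.09 (SE), Slc2a4 -1.16 ± 0.08, mt-Nd5 -1.07 ± 0.13 and Myh4 -1.52 ± 0.20. Camera adjusted p ran from 4.46e-08 for oxidative phosphorylation to 3.34e-04 for mitochondrially encoded genes, and from adjusted p = 0.41 to adjusted p = 0.46 with an estimated correlation. Integrin adhesion genes rose in 13 of 25 cases and 5 fell (13 and 5 adjusted over the list alone; adjusted p = 0.054), led by Itga5 (1.16 ± 0.09) and Itgav (1.35 ± 0.10). That list passed without WT replicate 3 (0.0478), 4 (0.0449) or 5 (0.0358), or mdxTG replicate 1 (0.0248) or 3 (0.0402), and with a filter of 2 CPM (0.0428). In the dystrophin-glycoprotein complex 4 of 16 genes rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.513), with Sntb2 at 0.87 ± 0.15. Of 21 YAP and TAZ targets 5 rose and 6 fell (5 and 6 adjusted over the list alone; adjusted p = 0.591), with Ankrd1 at 3.25 ± 0.30 and Crim1 at -1.15 ± 0.16. In plain CPM 14 of these targets rose and 2 fell, as did 19 and 1 integrin adhesion genes, 11 and 1 genes of the dystrophin-glycoprotein complex and 19 and 0 ribosomal protein genes. Nerve and Schwann cell genes fell in 5 of 12 cases with the authors' scaling (5 adjusted over the list alone, adjusted p = 0.0551). The nerve list passed without WT replicate 3 (0.0172), WT replicate 4 (0.0192) or mdxTG replicate 2 (0.0326). It also passed downward in plain CPM (0.00359), but relative to the other genes, since the median of all genes there shifted to 0.36. Endothelial genes fell in 6 of 12 cases (5 adjusted over the list alone; adjusted p = 0.107), rose in 3 in plain CPM, and passed as a list without WT replicate 1 (0.0323) or both WT replicates 1 and 2 (0.0385). The remaining 13 tested lists did not pass, with adjusted p from 0.223 to 0.96. Of these, slow fibres passed downward relative to the other genes in plain CPM (0.0338), where 4 of its genes rose and 2 fell, and ribosomal proteins without both WT replicates 1 and 2 (0.00651). The fry test passed integrin adhesion (adjusted p = 1.48e-04), the dystrophin-glycoprotein complex (1.58e-04), muscle atrophy (1.58e-04) and TGF-beta signalling (0.0235) upward. It passed endothelial cells (0.0485) and nerve and Schwann cells (0.0485) downward.

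The 10 largest rises were Mt3, Anxa8, Msln, Lgals3, Atp13a4, Mt2, Ahnak2, Atp6v0d2, Serpinb1a and Uchl1, with log2 folds from 7.10 ± 0.14 for Mt3 to 4.28 ± 0.18 (SE) for Uchl1. The largest falls included Pttg1, at 1.2 ± 0.282 normalized CPM in mdxTG and 52.1 ± 8 in WT, the noncoding 2310065F04Rik (6.51 ± 0.729 and 150 ± 19.6), Ppp1r1a (1.42 ± 0.266 and 34 ± 10.6) and Mettl11b (1.56 ± 0.492 and 28.8 ± 2.94). The zinc-finger genes Zfp970, Gm14326, Gm14325 and Zfp971 had 7, 5, 4 and 1 reads over the mdxTG libraries and 3229, 2894, 2465 and 2346 over the WT libraries. Of 1700001O22Rik 8 and 1939 reads were counted, and Myl3 had 5.78 ± 2.66 and 194 ± 313 normalized CPM, with WT replicate 1 the highest. In this comparison 5973 of the 13831 genes tested (43.2%, 1.59% by chance) had no overlap between the groups, 5854 of them among the changed genes. Of the changed genes 53.1% were higher in normalized CPM against 87.0% in plain CPM, where the median of all genes shifted to 0.36.

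**Figure D3:**
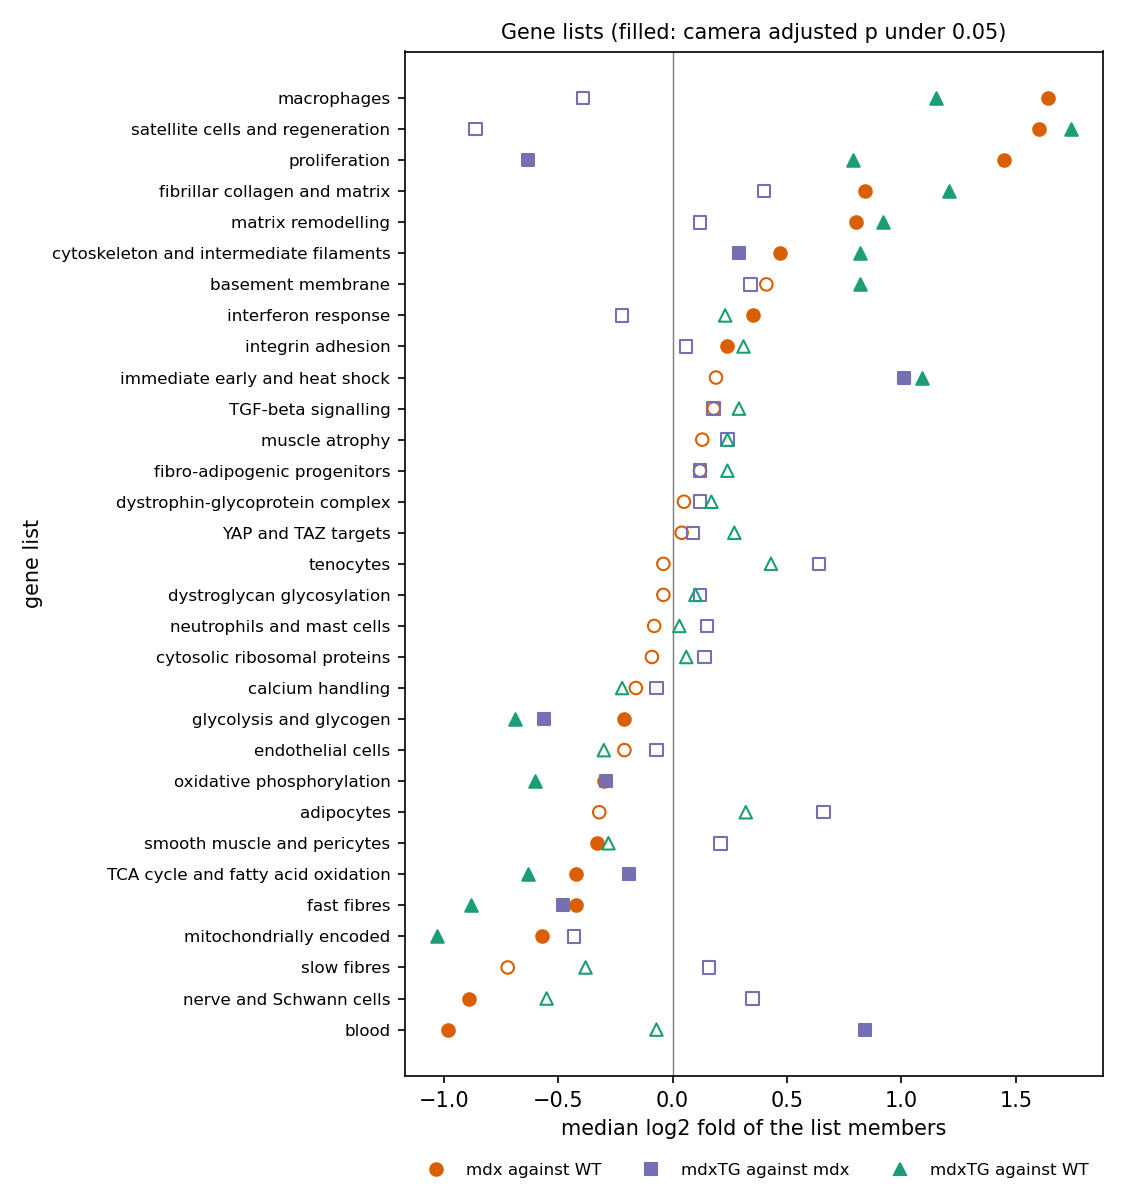
Median log2 fold of the tested members of each gene list in mdx against WT (circles), mdxTG against mdx (squares) and mdxTG against WT (triangles); filled symbols mark lists with a camera adjusted p under 0.05. Filled symbols mark 16, 8 and 13 lists, and 0 lists in each comparison would be filled with an estimated correlation.

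The signs of median, mean and test parted for neutrophils and mast cells and calcium handling in mdx against WT, and for calcium handling and adipocytes in mdxTG against WT. They also parted for matrix remodelling and neutrophils and mast cells in mdxTG against mdx. In plain CPM the median turned sign in 13 pairs of list and comparison, among the lists past the threshold only for glycolysis in mdx against WT.

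The last comparison asked how genes changed in mdx moved with the transgene. Of the 4782 genes changed in mdx, 693 (14.5%) moved back toward WT in mdxTG, 1166 (24.4%) moved further from WT, and 2923 (61.1%) did not pass in mdxTG against mdx. Regeneration and proliferation genes were among those that moved back, 11 of 19 and 10 of 17 changed genes, with 4 and 0 moving further. Macrophage genes moved back in 6 of 18 cases and further in 2. Cytoskeleton genes moved further in 7 of 15 cases and glycolysis genes in 6 of 8, with 0 moving back in either list, and TCA cycle and fatty acid oxidation genes moved further in 8 of 20 and back in 2. Of the genes that moved back, 383 no longer passed against WT, 230 still did on the same side and 80 passed on the other side.

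Genes that rose in mdx and fell in mdxTG numbered 433, where independent lists would share 331, and those that fell and then rose numbered 260 against 342.8. Genes that rose in both numbered 617 against 394.6, and those that fell in both 549 against 287.5. With simulated mdxTG libraries unchanged from mdx, a mean of 0.04 genes moved back. Without a transgene effect few genes can pass in mdxTG against mdx, and the simulation drew each gene independently. This count therefore does not show how the shared mdx libraries act on genes that do change. The covariance of the log2 folds across genes was 2.275e-04, against -0.0118 simulated without a transgene effect (r 9.322e-04 against -0.144), a difference of 0.012. With the mdx libraries divided between the comparisons the covariance ran from -0.00786 to 0.0351, the genes moving back from 258 to 420 and those moving further from 514 to 1020. The number moving back was 460 without mdx replicate 4, and in plain CPM 1808 genes moved further.

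**Figure D4:**
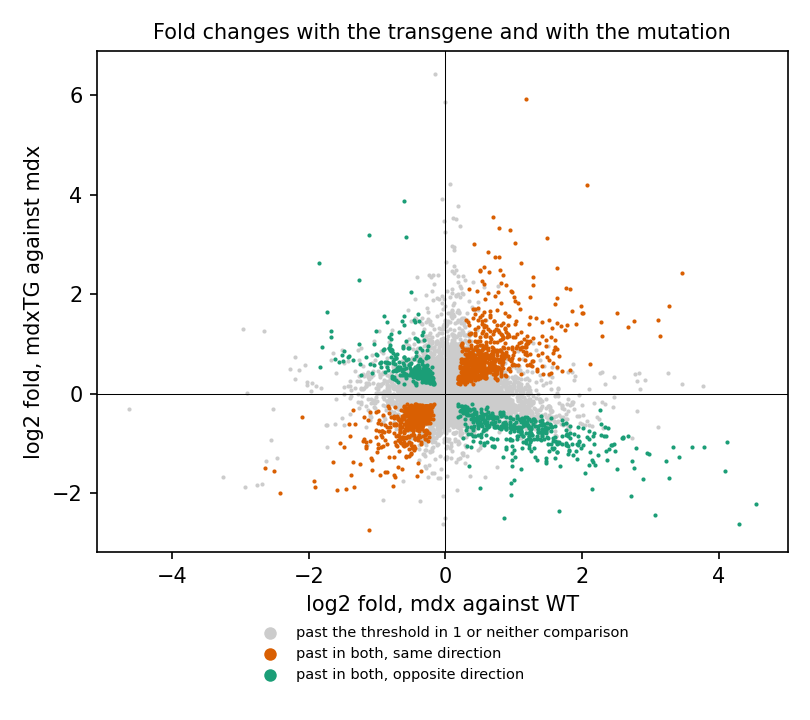
Log2 fold of each tested gene in mdx against WT (horizontal) and in mdxTG against mdx (vertical). Coloured points passed in both comparisons, 693 in opposite directions and 1166 in the same direction.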

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

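In this part the haplotype test, the slower-muscle test and the tenocyte test were chosen after the results they bear on had been seen, and the other tests before. The values of 141 genes, and measures of the libraries such as reads and scaling factor, were examined in each genotype. Of these 440 groups of values, 42 held 1 library whose gap to the nearest other library of its group was large for the range of the group. Chance flags about 1 in 20 groups, and correlated genes go out of line together. All flagged values are those of genes, in normalized CPM, each with the range of the other libraries of its group, and the group is the one that the library belongs to.

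In WT replicate 1 the value stood apart for the slow-fibre genes Myh7 (2578, others 12.4 to 75.1), Myl2 (856, others 13 to 66.4) and Myl3 (753, others 44.3 to 69.8), for the fast oxidative myosin Myh2 (4334, others 898 to 1583), and for mt-Co2 (26.6, others 3.18 to 7.91), Ampd3 (26.4, others 13 to 14.9), Nqo1 (27.3, others 16.8 to 19.6) and Gadl1 (16, others 6.37 to 8.48), all high, and for Ajuba (4.4, others 5.14 to 5.41), low. WT replicate 2 was low in Dmd (124, others 244 to 255), Dtna (103, others 133 to 137) and Hspa5 (137, others 173 to 177). It was high in Pvalb (14338, others 7846 to 9572), Hba-a1 (45.2, others 19 to 24.2), Gadd45a (22.7, others 16.5 to 18.3) and Ccl5 (0.464, others 0.0996 to 0.184). WT replicate 3 was high in Myh3 (39.2, others 3.03 to 5.97), Myh8 (10.8, others 3.5 to 4.72), Mymk (3.81, others 0.0597 to 0.212), Top2a (1.87, others 0.483 to 0.777), Tubb6 (24.3, others 10.8 to 13.7) and Sprr1a (0.21, others 0), and WT replicate 5 in Anxa8 (5.54, others 1.93 to 2.7).

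Among mdx libraries, replicate 1 was high in 1700001O22Rik (2.71, others 0.668 to 0.832) and Perp (1.55, others 1 to 1.09) and low in Arpp21 (12.5, others 17 to 17.6). Replicate 2 was high in Mt2 (199, others 42.1 to 45.5), Ankrd1 (201, others 77.1 to 86.6) and Btg2 (25.3, others 21.3 to 21.9), and replicate 4 in Ccl5 (1.52, others 0.48 to 0.635). Among mdxTG libraries, replicate 1 was high in Atp13a4 (53.4, others 23.8 to 26.5) and Gsta1 (10.9, others 6.49 to 6.9). Its values for Fgfbp1 (0.167, others 0.0336 to 0.0395), Gm14326 (0.0417, others 0.0168 to 0.0197), Zfp971 (0.0208, others 0) and 9930111J21Rik2 (0, others 0.0336 to 0.0395) rest on a few reads. Replicate 3 was high in Atp5a1 (1818, others 1565 to 1585), Pygm (3354, others 3003 to 3057), Fabp3 (218, others 149 to 153), Fam57b (12.4, others 7.3 to 7.6) and Mettl21c (12.2, others 5.29 to 6.39), and replicate 4 in Mymk (6.2, others 4.29 to 4.46).

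Zinc-finger genes of distal chromosome 2 were near 0 in all 4 mdxTG libraries and in mdx replicates 2 and 3, while Zfp970 was at 14.6 to 16.9 normalized CPM in WT and at 4.91 and 5.68 in mdx replicates 1 and 4. Reads shifted among the 13 listed genes within 1 Mb of Zfp970 would leave their sum in place. That sum was 87.5 ± 11.5 in WT and 13.3 ± 1.32 in mdxTG, 6.59-fold apart, which argues against a shift among these genes. Reads moved to copies outside them, or left uncounted as multiply mapped, would lower the sum, so the test cannot decide on those. A variant haplotype carried by some of the animals stays open: among 316 other genes that spanned at least 3 log2 units, 9 correlated over 0.9 with Zfp970 across the libraries and 7 of these (77.8%) lay within 5 Mb of it, against 9 (2.85%) of the 316, and 4 of these 7 had already been seen among the largest falls. The values of mdx replicates 1 and 4, between those of the other mdx libraries and WT, may then be those of 1 copy, which was not tested, and a biological effect of the genotype on these genes was not separated from strain background.

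Slow-fibre genes stood far above the other WT libraries in WT replicate 1, with Myh7 at 2578 normalized CPM against 12.4 to 75.1. Depth or scaling of this library would raise other genes alike, but its ribosomal protein genes lay only 0.18 above the other WT libraries in the median on the log2 scale, while the genes of the slow-fibre list lay 3.84 above them, or 3.87 without Myh2. Tissue of a slower neighbouring muscle and a higher share of slow fibres in the muscle itself cannot be told apart: that 13 of the 14 genes of the list (92.9%), or 12 of 13 without Myh2, had their highest WT value in this library restates the pattern and speaks for neither. All 14 genes, of which Mybpc1 (mean 3010 over the 13 libraries) and Myh2 (1210) are the most abundant, reached 0.5 normalized CPM in every library and 0 are in another list; no biological explanation was tested.

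Matrix and tendon genes varied together between libraries of one genotype along an axis that held 38.5% of the variance within groups, with Angptl7, Fmod, Chad and Comp among the 20 highest loadings. Whether the amount of tendon or connective tissue varied stays open: the median loading of the 9 tenocyte genes lay at the 99.8th percentile of all genes, also without the 4 among the 20 highest, but the fibrillar collagen and matrix list lay at the 98.9th, so the test is not specific to tendon. Gene length or RNA integrity also stays open, with a Spearman correlation of 0.42 between loading and exonic length across genes, which are not independent replicates. Length went little with the differences between genotypes (rho 0.09, -0.05 and 0.03 in mdx against WT, mdxTG against mdx and mdxTG against WT), whereas the loadings went with them at rho 0.26, 0.05 and 0.25. All 9 tenocyte genes, with Thbs4 (mean 317) and Fmod (251) the most abundant, reached 0.5 normalized CPM in every library, 1 is in another list, and no biological explanation was tested.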

How the results depend on the processing

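The alternatives chosen after the data were seen were plain CPM, the replicate block with only 2 groups, and leaving out WT replicates 1 and 2 together. No named gene and no list past the threshold reversed, and 166 sign changes concerned values past it in neither setting. For lists this compares the camera direction, which is relative to the other genes, so it cannot show a shift of all genes. In plain CPM the list median turned sign in 13 pairs of list and comparison. Among lists past the threshold this concerned only glycolysis in mdx against WT. Of 12740 values of genes named by the rule or in the text under alternatives 151 lost and 159 gained a call, and of 2108 list values 66 lost and 70 gained one. With an estimated correlation 0, 0 and 0 lists passed in mdx against WT, mdxTG against mdx and mdxTG against WT, in place of 16, 8 and 13, with estimated correlations of 0.03 to 0.90 against the preset 0.01 (3, 2 and 3 lists at an unadjusted p under 0.05). With the replicate block in a fit of only 2 groups 14 lists passed in mdxTG against mdx, and in plain CPM 1808 genes moved further; the cause was not tested. The counts of changed genes stayed within 1.5 times of 4782, 3922 and 7468 under every alternative run, with 4909, 4110 and 7556 under the replicate block, 5273, 4489 and 7806 with DESeq2, and 5889, 4487 and 9100 in plain CPM. Same-numbered libraries of mdxTG and mdx correlated at 0.41, -0.36, -0.19 and 0.32 and those of mdxTG and WT at 0.24, -0.47, -0.17 and 0.10, so they share only a number; the block passed 12 lists in mdxTG against mdx.

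Leaving out 1 library gave 3768 to 5257, 3038 to 4593 and 6537 to 7819 changed genes, 14 to 17, 7 to 11 and 12 to 15 lists, log2 folds of 3.85 to 3.96 for Sspn (mdxTG against mdx) and -2.23 to -1.97 for Dmd (mdx against WT), and a covariance of -0.0137 to 0.0071. The genes that moved back numbered 460 without mdx replicate 4 and up to 804 without WT replicate 2, and those that moved further 903 to 1381. Genes under 3 reads per library in a group, such as Atp13a4 in WT and mdx, had too little depth there for a precise fold.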

Other observations

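The lists of this part and their tests were set after the largest fold changes of mdxTG against mdx had been seen, before the values of the list members were looked at. Genes known to respond to p53 rose in mdxTG against mdx in 10 of 15 cases and 0 fell, among them Eda2r (log2 fold 2.05 ± 0.14 SE), the kinase Plk2 (1.42 ± 0.16), Btg2 (0.63 ± 0.10) and the stress cytokine Gdf15 (0.87 ± 0.15), those with the smallest p, as for each list below. Targets of the oxidative stress factor NRF2 rose in 7 of 13 cases and 3 fell, with Pgd at 1.07 ± 0.07, sulfiredoxin Srxn1 at 1.99 ± 0.20, the quinone reductase Nqo1 at 1.48 ± 0.16 and Gstm1 at -0.54 ± 0.08. Genes of endoplasmic reticulum stress and ATF4 rose in 9 of 17 cases and 1 fell, with the chaperone cofactor Dnajb9 at 0.61 ± 0.08, Manf at 0.72 ± 0.10, Vldlr at -0.54 ± 0.09 and Hspa5 at 0.54 ± 0.09. Genes known from denervated muscle rose in 6 of 11 cases and 1 fell, with the collagen tail of acetylcholinesterase Colq at 1.95 ± 0.15, Ampd3 at 1.32 ± 0.17 and Arpp21 at 0.78 ± 0.14.

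As a hypothesis, the large rises of Mt3, Anxa8, Uchl1, Perp and Gsta1 in mdxTG may belong to a stress or denervation-type response. Over the 4 lists camera gave an adjusted p of 0.00112 for p53 targets, 0.0221 for NRF2 targets, 0.0298 for endoplasmic reticulum stress and ATF4, and 0.0347 for denervation. With an estimated correlation the adjusted p was 0.012, 0.21, 0.21 and 0.21, so of the 4 only the p53 list passed, without each library in turn too (adjusted p = 0.012 to adjusted p = 0.018), but not in plain CPM (adjusted p = 0.067). The adjustment here was over 4 lists set after the largest folds had been seen, against 31 for the lists fixed beforehand. The p53 list therefore did not meet the same hurdle as those 31. At the preset correlation plain CPM left p53 targets past the threshold (adjusted p = 0.00355) and not NRF2 targets (adjusted p = 0.0553), endoplasmic reticulum stress and ATF4 (adjusted p = 0.0563) or denervation (adjusted p = 0.0755), while the 4 medians stayed positive (0.64, 0.56, 0.37 and 0.55, with 0.13 for all genes). The denervation list also missed it without mdx replicate 1 (adjusted p = 0.0671) or mdxTG replicate 2 (adjusted p = 0.0508), and NRF2 targets passed with an estimated correlation without mdx replicate 2 (adjusted p = 0.041). The list medians lay at the 100th, 100th, 99.6th and 99.9th percentile of 10000 random lists matched on expression, but their bootstrap intervals reached -0.02, -0.19, -0.11 and -0.02. Members of the random lists were drawn independently of each other, so the percentiles take no account of correlation between the genes of a list. In mdx against WT the denervation list was already higher (adjusted p = 3.15e-04, and adjusted p = 0.087 with an estimated correlation). The tests do not tell these responses apart, and they do not show which cells they come from.

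The numbers of changed genes were set against other splits of the same libraries. In mdx against WT 1 of 100 splits, the real one, gave 4782 genes, and the highest other, which differs from it only in moving WT replicate 2 to the mdx side, gave 3278. The WT and mdx numbers may pair the libraries, which rests on their correlations and not on the labels. Among the 14 splits drawn that part every such pair, the real one included, the highest other gave 3186. It moves WT replicate 5 to the mdx side. If the numbers do pair the libraries, these 14 splits are too few for a share under 0.05. In mdxTG against mdx 1 of 35 splits, the real one, gave 3922, and the highest other gave 0 with limma, or 1694 against 5397 at an unadjusted p under 0.05. In mdxTG against WT 1 of 100 splits, the real one, gave 7468, and the highest other, which differs from the real one only in moving WT replicate 5 to the mdxTG side, gave 5403. The real division alone reached the count in mdxTG against mdx (1 of 35 splits) and in mdxTG against WT (1 of 100). These shares are the smallest that the splits allow, so they argue against a chance division without excluding it. The splits also treat each library as an independent sample, which the labels do not say. The splits do not separate genotype from anything else that differs between the groups.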
